A study of Homo sapiens with 24 samples.

How the data were processed

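The deposited table of 24 arrays gives, per the file headers, an average signal intensity for each probe on each array, not normalized between arrays. Background had been subtracted from it, as values below 0 occur. The same deposited table gives a detection p-value for each probe on each array, per the file headers. The signals were summarised in GenomeStudio per the submitters' processing notes, and the version is not given in the sources used here. A second deposited table holds signal intensity normalized between arrays on a linear scale by a method not given in the sources used here, and it was used only as an alternative to the values computed here. It held 38221 of the 47231 probes, its array medians lay between 4.80 and 4.90 after log2 transformation, and its log2 values correlated over probes with the values computed here at r = 0.995 to r = 0.998 per array. No control probes were used, so remaining background was estimated from the detection p-values.

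Signals of each line were corrected for remaining background, quantile normalized and put on the log2 scale with neqc of limma 3.58.1 (offset 16) in R 4.3.3, with data.table (version 1.17.8) for reading tables and matplotlib 3.10.9 for the figures. Of the 47231 probes, 27007 were matched to a human gene, 27003 of them to 1 symbol and 4 to several, and 20224 had no gene symbol here and were only counted. Current symbols were found by gene identifier for 26969 probes, and 34 kept an older symbol. A probe was kept in a line when its detection p was below 0.01 on at least 3 of the 12 arrays of that line. Each gene was read by its brightest kept probe. That left 9569 genes in WM35 and 9292 in Mel-624.

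Each line was fitted on its own with lmFit and eBayes of limma, with 4 group means of 3 arrays each. From each fit came the treatment effect in normoxia, in hypoxia and averaged over both, the hypoxia effect without and with treatment, and the interaction, which is the treatment effect in hypoxia minus that in normoxia. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all tested genes of that comparison. All effects are log2 fold changes with the standard error after the ± sign. In simulated data of the same size, 25 of 50 genes changed 1.5-fold and 45 of 50 changed 2-fold were called for the IGF1 effect in normoxia, against 29 of 50 and 49 of 50 for the siIGF1R effect in normoxia. Wrong calls made up 3.73% and 6.80% of all calls in those 2 runs. The simulated spread was independent between genes. In the real arrays 1 axis carried 31.3% of the spread within groups in WM35 and 19.7% in Mel-624. The simulated shares may therefore not hold for the real data.

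The 25 fixed gene lists, written before the data were examined, held hypoxia-inducible genes, glycolytic enzymes, growth factor early response and ERK feedback genes, FOXO target genes, sterol and fatty acid synthesis genes, ATF4 and amino acid response genes, ER chaperone genes, heat shock genes, ribosome biogenesis genes, ribosomal protein genes, oxidative phosphorylation genes, DNA replication and G1/S genes, G2/M and mitosis genes, melanocyte differentiation genes, mesenchymal and invasive melanoma genes, interferon response genes, NF-kB and inflammatory genes, BCL2 family and caspase inhibitor genes, p53 target genes, IGF axis genes, histone genes, and marker genes of fibroblasts, of keratinocytes and epithelium, of immune cells and of endothelium. Lists were tested with camera of limma, with the correlation between genes estimated from the data, and p-values were adjusted over the 25 lists of a comparison. The preset correlation of 0.01 and the rotation test fry served as alternatives. Every list called with the estimated correlation was also called with the preset one, and 45 calls were made with the preset one only.

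Genes were named by a rule fixed before the data were examined. It covers the fixed genes IGF1R, INSR, IRS1, IRS2, IGF1, CA9, VEGFA, SLC2A1, ADM and NDRG1. It also covers, per comparison, the 10 largest rises and 10 largest falls among called genes whose 3 arrays of one group all lay outside the range of the other 3. For the averaged effect that had to hold at both oxygen levels, and for an interaction no range was asked for. From each described list up to 4 members with the smallest p were added. XIST and Y-linked genes were tested and counted but are not reported singly. Where 1 group was not detected on any of its arrays, the change is given as at least a fold, taken against that group's mean signal, with each signal raised to the lowest detected signal of its array where it lay below it.

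Choices made before the data were examined were no further background correction, the deposited normalized values, detection on all 12 arrays, no detection filter, the mean of a gene's probes, the replicate letter as a block, each array left out in turn, only the arrays of the groups compared, a fold change of at least 1.5, and the 2 other list tests. Leaving out the WM35 libraries standing furthest apart, removing the main within-group axis, and the list tests with each array left out were added after the data were seen.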

Results

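Transcript levels were measured on Illumina expression BeadChips in WM35 and Mel-624, human melanoma cell lines, in order to define how their transcriptomes answer to insulin-like growth factor 1 (IGF1) signalling in normal and in low oxygen. The 24 arrays formed 8 groups of 3, labelled A, B and C. WM35 cells were kept for 24 h at 21% oxygen (normoxia) or 1% oxygen (hypoxia) and were left untreated or given recombinant human IGF1 at 100 ng/mL for 6 h before harvest. Mel-624 cells were transfected with a pool of siRNAs against the IGF1 receptor (siIGF1R) or with a non-targeting pool (siControl) and kept for 3 days at either oxygen level. Labelled RNA was prepared from 300 ng of total RNA per sample. Between 13948 and 15987 of the 47231 probes were detected per array, at least 29.5%. The signal before normalization averaged 331 ± 12.4 (SD, n = 3) in the WM35 normoxia controls and between 256 and 260 in the means of the 3 other WM35 groups, against 309 to 342 in the Mel-624 groups. The labels do not say whether replicates were separate cultures, so p-values measure the spread between samples, which may be technical, and the number of arrays limits their precision. Each line was on a BeadChip of its own, so line and chip cannot be told apart. The arrays of a group lay at consecutive positions on the chip in WM35, and nearly so in Mel-624. Position on the chip was therefore not separated from group.

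All effects are log2 fold changes ± SE with n = 3 arrays per group, and p-values are adjusted. In every gene given below as having risen or fallen in a comparison of 2 groups, all 3 arrays of one group lay beyond the 3 of the other. INSR was detected on at most 1 of the 12 arrays of a line and IGF1 on 0, so neither was tested, and CA9 had no named probe.

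The first question was which genes answered to added IGF1 in WM35 in normoxia. The heat shock gene HSPA1B rose by 1.31 ± 0.09 (adjusted p = 1.5e-05), though its probe cannot be separated from the near-identical HSPA1A. SPRY1, an inhibitor of growth factor signalling, rose by 1.35 ± 0.13, DDIT4, a restraint on the growth kinase mTORC1, by 0.98 ± 0.11, and SCD, a fatty acid desaturase, by 0.74 ± 0.09. Falls were seen for ABTB1 (-1.44 ± 0.13, adjusted p = 0.00016), for YPEL3, a growth-suppressing gene (-1.18 ± 0.13), for SAT1, which degrades polyamines (-0.90 ± 0.11), and for PDE4B, a cyclic AMP phosphodiesterase gene (-0.87 ± 0.12). PDGFRB, a growth factor receptor, fell at least 1.45-fold and was not detected after IGF1. IGF1R itself moved by 0.03 ± 0.13, with levels of 6.67, 6.30 and 6.36 in the controls and 6.44, 6.56 and 6.42 with IGF1.

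Among gene groups after IGF1 in normoxia, heat shock genes had 3 members up and 0 down of 12 tested (6 and 0 adjusted over the list alone, median 0.31, camera adjusted p = 0.0076). Ribosome biogenesis genes had 2 up and 0 down of 24 (10 and 0 adjusted over the list alone, median 0.25, camera adjusted p = 0.0076). Hypoxia-inducible genes had 4 up and 0 down of 26, BHLHE40 (0.78 ± 0.11) among them (8 and 1 adjusted over the list alone, median 0.18, camera adjusted p = 0.0076). AK4, which is not on that list, rose by 0.85 ± 0.12. Sterol and fatty acid synthesis genes had 3 up of 22 and ER chaperone genes 1 up of 15, with 0 down in both (6 and 1, and 7 and 0, adjusted over the list alone), medians of 0.16 and 0.17 and camera adjusted p = 0.019 for both. FOXO target genes, which insulin-like signals repress, had 0 up and 4 down of 20 (0 and 5 adjusted over the list alone), with adjusted p = 0.064 with an estimated correlation and 0.0011 with the preset one. Normoxia control C and hypoxia control A stood furthest from their groups on the main axis of spread within groups, with scores of 11.25 and 14.73. Hypoxia IGF1 C stood nearly as far in the same direction (10.97) and was kept, so leaving out the 2 libraries removed control arrays only. Without those 2 libraries adjusted p = 0.042 for heat shock genes, adjusted p = 0.020 for ribosome biogenesis genes and adjusted p = 0.073 for the 3 other called lists. Over all alternatives with an estimated correlation, adjusted p of the 5 lists ranged from 0.0059 to 0.073. Sterol and ER chaperone genes also had adjusted p = 0.055 without normoxia control C alone.

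In all, 151 of the 9569 WM35 genes were called in normoxia, 66 up and 85 down, and all 151 had non-overlapping arrays. Of unselected genes 10% would by chance, but calls rest on the same arrays, so that separation is no independent support. The count was 26, 32 and 82 without normoxia control A, B and C, 67 and 46 without normoxia IGF1 B and C, 73 without hypoxia control B, and 77 and 97 without hypoxia IGF1 B and C. It was also 87 with the replicate letter as a block, 31 with only the arrays of the groups compared, 90 with no detection filter and 249 with detection on all 12 arrays. At an unadjusted p under 0.05 there were 1778 genes.

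The same treatment was then asked about in hypoxia. HSPA1B rose by 1.62 ± 0.09 (adjusted p = 1.1e-06), CTH, an enzyme of cysteine synthesis, at least 1.75-fold from undetected, and SLC6A9, a glycine transporter, by 0.98 ± 0.14. Falls were seen for the non-coding RNA SLCO4A1-AS1 (-1.52 ± 0.12), YPEL3 (-1.32 ± 0.13), SNHG7 (-1.25 ± 0.12), SAT1 (-1.03 ± 0.11), the GTPase gene RHOU (-1.07 ± 0.14) and FBXO32, a FOXO-driven ubiquitin ligase gene (-0.83 ± 0.10). IGF1R levels were 6.04, 6.35 and 6.16 in hypoxia controls and 6.27, 6.27 and 5.98 with IGF1. Of 867 called genes, 431 rose and 436 fell, and 865 had non-overlapping arrays. The count was 430 and 519 without hypoxia control B and C, and 539, 361 and 406 without hypoxia IGF1 A, B and C. With only the arrays of the groups compared it was 436.

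Gene groups of biosynthesis and protein folding rose with IGF1 in hypoxia. ATF4 and amino acid response genes, which raise amino acid supply, had 14 up and 0 down of 28 (19 and 1 adjusted over the list alone, median 0.48, camera adjusted p = 0.0048), with PSAT1 at 0.68 ± 0.10, PSPH at 0.82 ± 0.13 and ATF3 at 0.74 ± 0.11. ER chaperone genes had 7 up and 0 down of 15 (7 and 0 adjusted over the list alone, adjusted p = 0.0048), HSPA5 rising by 0.82 ± 0.09 and SDF2L1 by 0.96 ± 0.13. Heat shock genes had 5 up and 0 down of 12 (7 and 0 adjusted over the list alone, adjusted p = 0.0048), among them HSPH1 (0.79 ± 0.09). Ribosome biogenesis genes had 7 up of 24 and DNA replication and G1/S genes 10 up of 26, with 0 down in both (10 and 0, and 12 and 0, adjusted over the list alone, adjusted p = 0.0088 for both). NOP56 rose by 0.57 ± 0.09 and the replication licensing gene MCM4 by 0.66 ± 0.09. Sterol and fatty acid synthesis genes had 6 up and 1 down of 22 (7 and 1 adjusted over the list alone, adjusted p = 0.025), with DHCR7 at 0.94 ± 0.12, INSIG1 at 0.69 ± 0.10 and TM7SF2 at -0.58 ± 0.11. Without hypoxia control B the list had adjusted p = 0.057, the highest over the alternatives, whose lowest was 0.019. Without the 2 libraries standing apart, adjusted p lay between 0.016 and 0.036 for these 6 lists.

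Mitotic genes moved the other way. G2/M and mitosis genes had 0 up and 8 down of 28 (0 and 15 adjusted over the list alone, median -0.28, camera adjusted p = 0.034), among them HMMR (-0.71 ± 0.10), DLGAP5 (-0.53 ± 0.08) and KIF20A (-0.52 ± 0.09). That list's adjusted p was 0.053 without normoxia control A, 0.051 and 0.055 without normoxia IGF1 A and C, 0.060 without hypoxia control B and 0.0504 without hypoxia IGF1 B, within a range of 0.013 to 0.078 over the alternatives. FOXO target genes had 0 up and 7 down of 20 (0 and 7 adjusted over the list alone), adjusted p = 0.056 with an estimated correlation and 0.0015 with the preset one. Hypoxia-inducible genes had 2 up and 0 down of 26, with a median of -0.04, a mean of -0.01 and a camera direction of up (adjusted p = 0.90).

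Averaged over both oxygen levels, IGF1 raised HSPA1B by 1.46 ± 0.06 (adjusted p = 5.2e-08), CTPS1, which makes cytidine nucleotides, by 0.74 ± 0.06, SCD by 0.70 ± 0.06 and the cholesterol synthesis gene DHCR7 by 0.77 ± 0.09. The angiogenic factor VEGFA rose by 0.40 ± 0.09 (adjusted p = 0.0091) and the vasodilator gene ADM by 0.33 ± 0.06. SLCO4A1-AS1 fell by 1.51, ABTB1 by 1.13 and SAT1 by 0.97. Of 1483 called genes, 724 rose and 759 fell. Heat shock genes (7 up of 12), ribosome biogenesis genes (11 of 24) and ER chaperone genes (8 of 15) had 0 down and adjusted p = 0.0061. ATF4 genes had 14 up and 1 down of 28 (adjusted p = 0.012), sterol genes 8 up and 2 down of 22 (adjusted p = 0.013) and DNA replication genes 11 up and 0 down of 26 (adjusted p = 0.013, 0.058 without both libraries standing apart and at most that over the alternatives). FOXO target genes (0 up, 6 down of 20), G2/M genes (0 up, 9 down of 28) and hypoxia-inducible genes (7 up, 1 down of 26) each had adjusted p = 0.047. Of the 12 fits with 1 array left out, FOXO genes kept adjusted p below 0.05 in those without normoxia control B, normoxia IGF1 A or B or hypoxia IGF1 C. G2/M genes kept it in those without hypoxia control A or hypoxia IGF1 A, and hypoxia-inducible genes in those without normoxia IGF1 B or hypoxia IGF1 A. In the other fits of the 12 the 3 lists had adjusted p of up to 0.083, 0.072 and 0.117. Over all alternatives with an estimated correlation, adjusted p ranged from 0.021 to 0.158 for FOXO genes and from 0.018 to 0.099 for G2/M genes. For hypoxia-inducible genes it ranged from 0.035 to 0.213.

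Effects of IGF1 at the 2 oxygen levels, which share no arrays, correlated over genes at r = 0.485, though genes are not independent. Of the called genes 82 changed the same way at both, where 6.85 would by independence, and 0 changed in opposite directions. Both calls used the same estimate of spread per gene, which can raise overlap in either direction above independence. The same holds for the other overlaps within a line. A direct test of the difference called 5 genes, 1 higher and 4 lower in hypoxia (823 at an unadjusted p under 0.05 in limma). That count was 0 without any 1 of the 6 normoxia arrays or of hypoxia IGF1 A and B, 9 and 2 without hypoxia control A and B, and 1 without hypoxia IGF1 C. It was 2 with the replicate letter as a block, 8 with the deposited values and 0 without both libraries standing apart. ATF4 genes differed by a median of 0.37 and hypoxia-inducible genes by -0.17 (camera adjusted p = 0.0093 for both). Without normoxia control C the latter had adjusted p = 0.051, and without both libraries standing apart adjusted p was 0.054 and 0.098, the highest over the alternatives, whose lowest were 0.00295 and 0.0091.

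**Figure D1:**
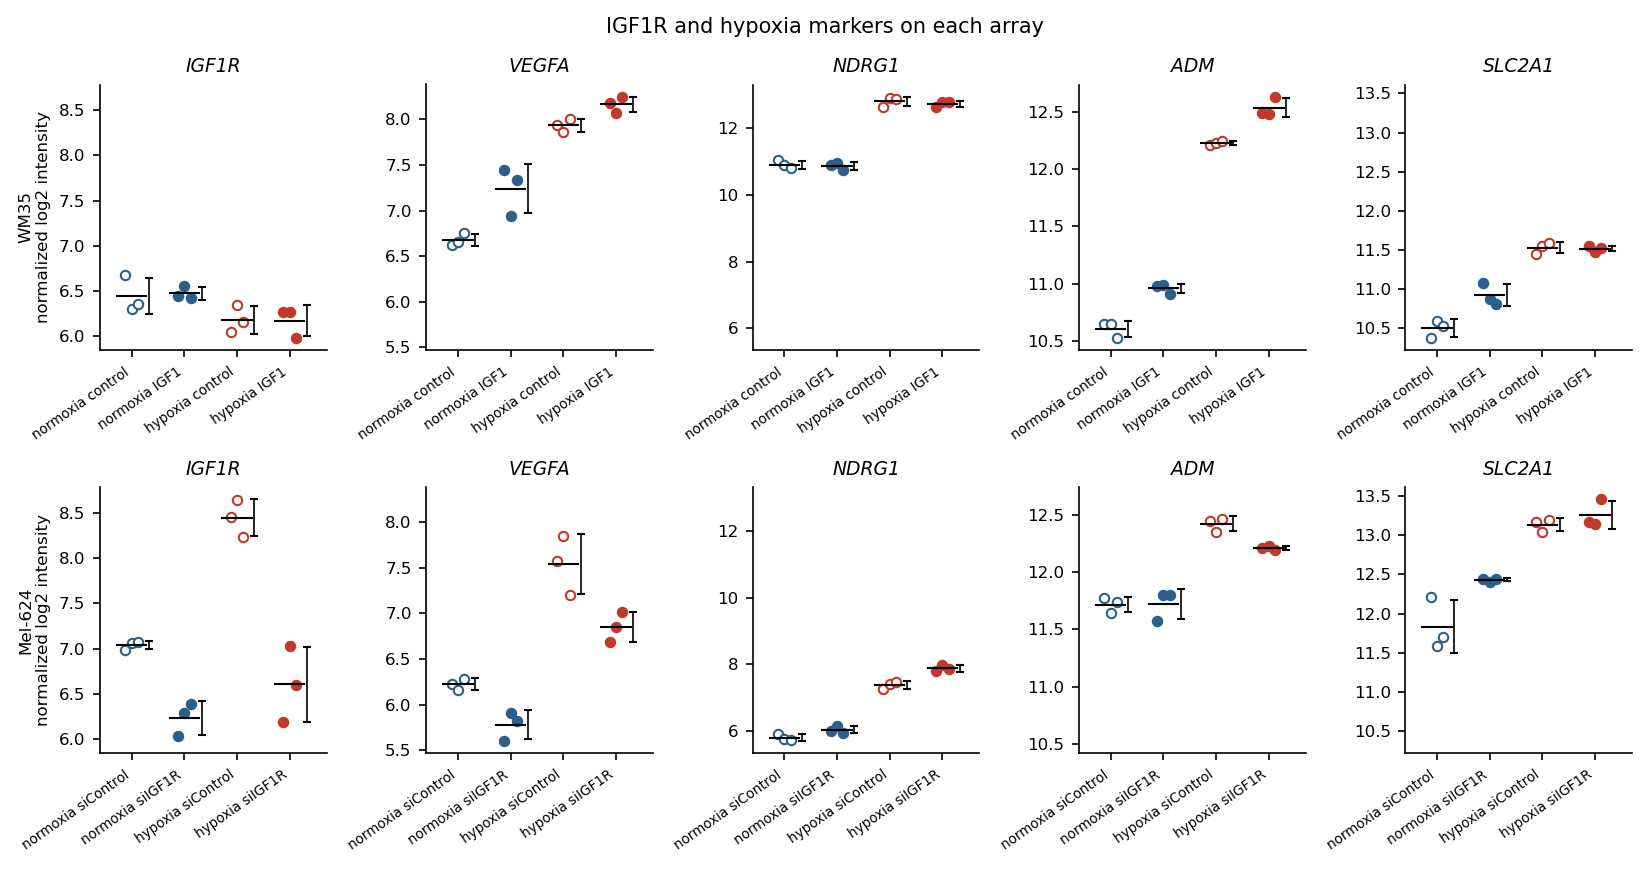
Log2 intensity of IGF1R, VEGFA, NDRG1, ADM and SLC2A1 on each array of WM35 (top) and Mel-624 (bottom), with 1 point per array, open for untreated or siControl, filled for IGF1 or siIGF1R, blue for normoxia and red for hypoxia, and with black lines for means and bars for the SD of 3 arrays. IGF1R in Mel-624 averaged 7.04 and 8.45 in siControl and 6.23 and 6.60 in siIGF1R cells in normoxia and hypoxia.

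How WM35 answered to low oxygen without added IGF1 came next. ANGPTL4, a secreted lipase inhibitor, rose by 5.79 ± 0.16 (adjusted p = 1.7e-10), and EPAS1, which encodes the hypoxia factor HIF-2 alpha, rose at least 11.1-fold from undetected. DDIT4 rose by 2.76 ± 0.11, the stress gene NDRG1 by 1.89 ± 0.11, ADM by 1.62 ± 0.08, VEGFA by 1.26 ± 0.12 and the glucose transporter SLC2A1 by 1.03 ± 0.10. Falls were seen for the tight junction gene CLDN1 (-2.40 ± 0.20), MRGPRX4 (-2.02 ± 0.10), the chemokine CCL2 (-1.36 ± 0.15) and KLF9 (-1.33 ± 0.09). Hypoxia-inducible genes had 24 up and 0 down of 26 (24 and 0 adjusted over the list alone, median 1.49, camera adjusted p = 3.3e-05), and glycolytic enzymes 13 up and 0 down of 17 (14 and 0 adjusted over the list alone, adjusted p = 0.00064), with ALDOC at 1.91 ± 0.08 and HK2 at 1.55 ± 0.10. DNA replication and G1/S genes had 0 up and 20 down of 26 (0 and 22 adjusted over the list alone, median -0.57, adjusted p = 0.0067), MCM6 by -0.83 ± 0.10 and PCNA by -1.14 ± 0.13. In all 1981 genes were called, 955 up and 1026 down, 1955 of them with non-overlapping arrays.

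Heat shock and ribosome biogenesis genes fell less firmly in hypoxic WM35 control cells. Heat shock genes had 0 up and 7 down of 12 (0 and 7 adjusted over the list alone, adjusted p = 0.035), HSP90AA1 by -0.77 ± 0.11. The list had adjusted p = 0.0501 without hypoxia IGF1 A, and its p ranged from 0.0085 to 0.060. Ribosome biogenesis genes had 1 up and 10 down of 24 (2 and 14 adjusted over the list alone, adjusted p = 0.040), RRS1 by -0.67 ± 0.10. Its adjusted p was 0.063, 0.053 and 0.053 without normoxia IGF1 A, B and C, 0.051 and 0.069 without hypoxia control A and C, and 0.061, 0.059 and 0.063 without hypoxia IGF1 A, B and C, ranging from 0.015 to 0.087. ER chaperone genes had 0 up and 3 down of 15 (0 and 5 adjusted over the list alone) and were not called as a list (adjusted p = 0.537). ATF4 genes had 2 up and 12 down of 28 (adjusted p = 0.083 with an estimated correlation, 0.0025 with the preset one).

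With IGF1 present, hypoxia raised ANGPTL4 by 5.52 ± 0.16, EPAS1 at least 12.8-fold, NDRG1 by 1.87 ± 0.11, ADM by 1.58 ± 0.08, VEGFA by 0.92 ± 0.12 and SLC2A1 by 0.60 ± 0.10. The matrix gene CCN2 (-1.82 ± 0.12) and CCL2 (-2.04 ± 0.15) fell. Hypoxia-inducible genes had 22 up and 0 down of 26 (23 and 0 adjusted over the list alone, adjusted p = 4.9e-05) and glycolytic enzymes 12 up and 0 down of 17 (14 and 0 adjusted over the list alone, adjusted p = 0.0010). DNA replication genes had 0 up and 9 down of 26 (0 and 12 adjusted over the list alone, adjusted p = 0.042) and ribosome biogenesis genes 0 up and 8 down of 24 (0 and 10 adjusted over the list alone, adjusted p = 0.045). Both had adjusted p above 0.05 without normoxia control A (0.057 and 0.057) or B (0.053 and 0.053), normoxia IGF1 C (0.0565 and 0.0565), hypoxia control A (0.061 and 0.061) or C (0.065 and 0.065), and hypoxia IGF1 A (0.059 and 0.066). DNA replication genes also did without normoxia control C (0.051), and ribosome biogenesis genes without normoxia IGF1 A (0.088) or B (0.086) or hypoxia IGF1 B (0.060) or C (0.095). Over the alternatives their p reached 0.096 and 0.097 and went down to 0.012 and 0.0215. G2/M genes had 0 up and 9 down of 28 (adjusted p = 0.055 with an estimated correlation, 1.2e-06 with the preset one). In all 1488 genes were called, 784 up and 704 down, 1477 with non-overlapping arrays. The count was 909 without hypoxia IGF1 B. Hypoxia effects without and with IGF1 correlated over genes at r = 0.756, with 956 genes called the same way (154 by independence) and 5 in opposite directions.

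In Mel-624 the question was what followed from lowering the IGF1 receptor. IGF1R stood at 6.98, 7.06 and 7.07 in normoxic siControl cells and at 6.03, 6.28 and 6.39 in siIGF1R cells, a fall of -0.81 ± 0.18 (adjusted p = 0.0099). In hypoxia it stood at 8.46, 8.65 and 8.24 against 6.19, 7.03 and 6.60, a fall of -1.84 ± 0.18 (adjusted p = 2.5e-05). The difference between those falls was -1.04 ± 0.25 (adjusted p = 0.078).

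In normoxia, knockdown raised COQ8A, a gene of coenzyme Q synthesis, by 1.43 ± 0.11 (adjusted p = 3.4e-05), ABTB1 by 1.27 ± 0.11, the retinoid receptor gene RXRG by 1.30 ± 0.09 and the lysosomal protease gene CTSL by 1.11 ± 0.10. CREBRF, a stress regulator, rose by 1.87 ± 0.20 and SLC6A15 by 1.48 ± 0.13, although 1 other probe of SLC6A15 was called down. The ribonuclease gene RNASE1 fell at least 2.11-fold to undetected, the calcium channel gene ORAI1 by -1.39 ± 0.16 and the centrin gene CETN2 by -1.07 ± 0.09. FOXO target genes had 11 up and 1 down of 24 (11 and 2 adjusted over the list alone), with PDK4, a brake on glucose oxidation, at 1.02 ± 0.11 and HBP1 at 0.78 ± 0.09, adjusted p = 0.065 with an estimated correlation and 0.0051 with the preset one. G2/M genes had 0 up and 8 down of 28 (0 and 16 adjusted over the list alone), with CENPA at -0.66 ± 0.09, adjusted p = 0.065 with an estimated correlation and 2.3e-07 with the preset one. Sterol genes had 0 up and 8 down of 23 (1 and 9 adjusted over the list alone), with LSS at -0.53 ± 0.09, adjusted p = 0.090 with an estimated correlation and 0.00012 with the preset one. With an estimated correlation camera called 0 of the 25 lists, and with the preset one 5. Of 9292 genes 1483 were called, 789 up and 694 down, 1466 with non-overlapping arrays. The count was 889 without normoxia siControl A and 916 without normoxia siIGF1R B.

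In hypoxia, knockdown raised COQ8A by 2.03 ± 0.11 (adjusted p = 1.1e-06), SLC6A15 by 1.90 ± 0.13, ABTB1 by 1.47 ± 0.11 and CDH19 by 1.46 ± 0.13. It lowered the small heat shock gene CRYAB (-2.19 ± 0.17), HSPA1B (-1.52 ± 0.12), the immediate early gene EGR1 (-1.56 ± 0.14), PXMP2 (-1.63 ± 0.10) and CETN2 (-1.52 ± 0.09). Sterol and fatty acid synthesis genes had 0 up and 17 down of 23 (0 and 17 adjusted over the list alone, median -0.48), with SQLE at -0.83 ± 0.08, DHCR7 at -1.12 ± 0.12 and ACLY at -1.06 ± 0.12. G2/M genes had 0 up and 15 down of 28 (0 and 18 adjusted over the list alone, median -0.31), with AURKB at -0.73 ± 0.10 and the proliferation marker MKI67 at -0.90 ± 0.13. DNA replication genes had 1 up and 13 down of 27 (1 and 14 adjusted over the list alone, median -0.31), with GINS2 at -0.88 ± 0.09 and CDC45 at -0.70 ± 0.09. Each of these 3 lists had camera adjusted p = 0.023 and adjusted p = 0.0505 without hypoxia siControl B. With the deposited normalized values adjusted p was 0.054, 0.054 and 0.078, the highest over the alternatives, whose lowest were 0.0018, 0.0018 and 0.0078. ATF4 genes had 2 up and 9 down of 25 (adjusted p = 0.055 with an estimated correlation, 0.013 with the preset one), with AARS1 at -0.98 ± 0.09. In all 2399 genes were called, 1220 up and 1179 down, 2350 with non-overlapping arrays.

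Averaged over oxygen, siIGF1R lowered IGF1R by -1.32 ± 0.13 (adjusted p = 1.2e-05) and VEGFA by -0.57 ± 0.11 (adjusted p = 0.0012). It raised COQ8A by 1.73 ± 0.08, ABTB1 by 1.37 ± 0.08 and TXNIP, a brake on glucose uptake, by 1.10 ± 0.07, and lowered CETN2 by -1.29 ± 0.06 and the desaturase gene SCD5 by -1.18 ± 0.07. Of 3218 called genes 1678 rose and 1540 fell. Sterol genes had 0 up and 18 down of 23 and G2/M genes 0 up and 22 down of 28 (1 and 19, and 0 and 24, adjusted over the list alone, adjusted p = 0.024 for both). DNA replication genes had 0 up and 11 down of 27 (0 and 13 adjusted over the list alone, adjusted p = 0.035). Their adjusted p was 0.070 without normoxia siControl C, 0.0775 and 0.070 without hypoxia siControl B and C, and 0.063, 0.064 and 0.058 without hypoxia siIGF1R A, B and C, at most 0.107 over the alternatives. That highest value came with the deposited values, which gave adjusted p = 0.080 for sterol genes. Effects at the 2 oxygen levels correlated over genes at r = 0.617, with 879 genes called the same way (192 by independence) and 9 in opposite directions.

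**Figure D2:**
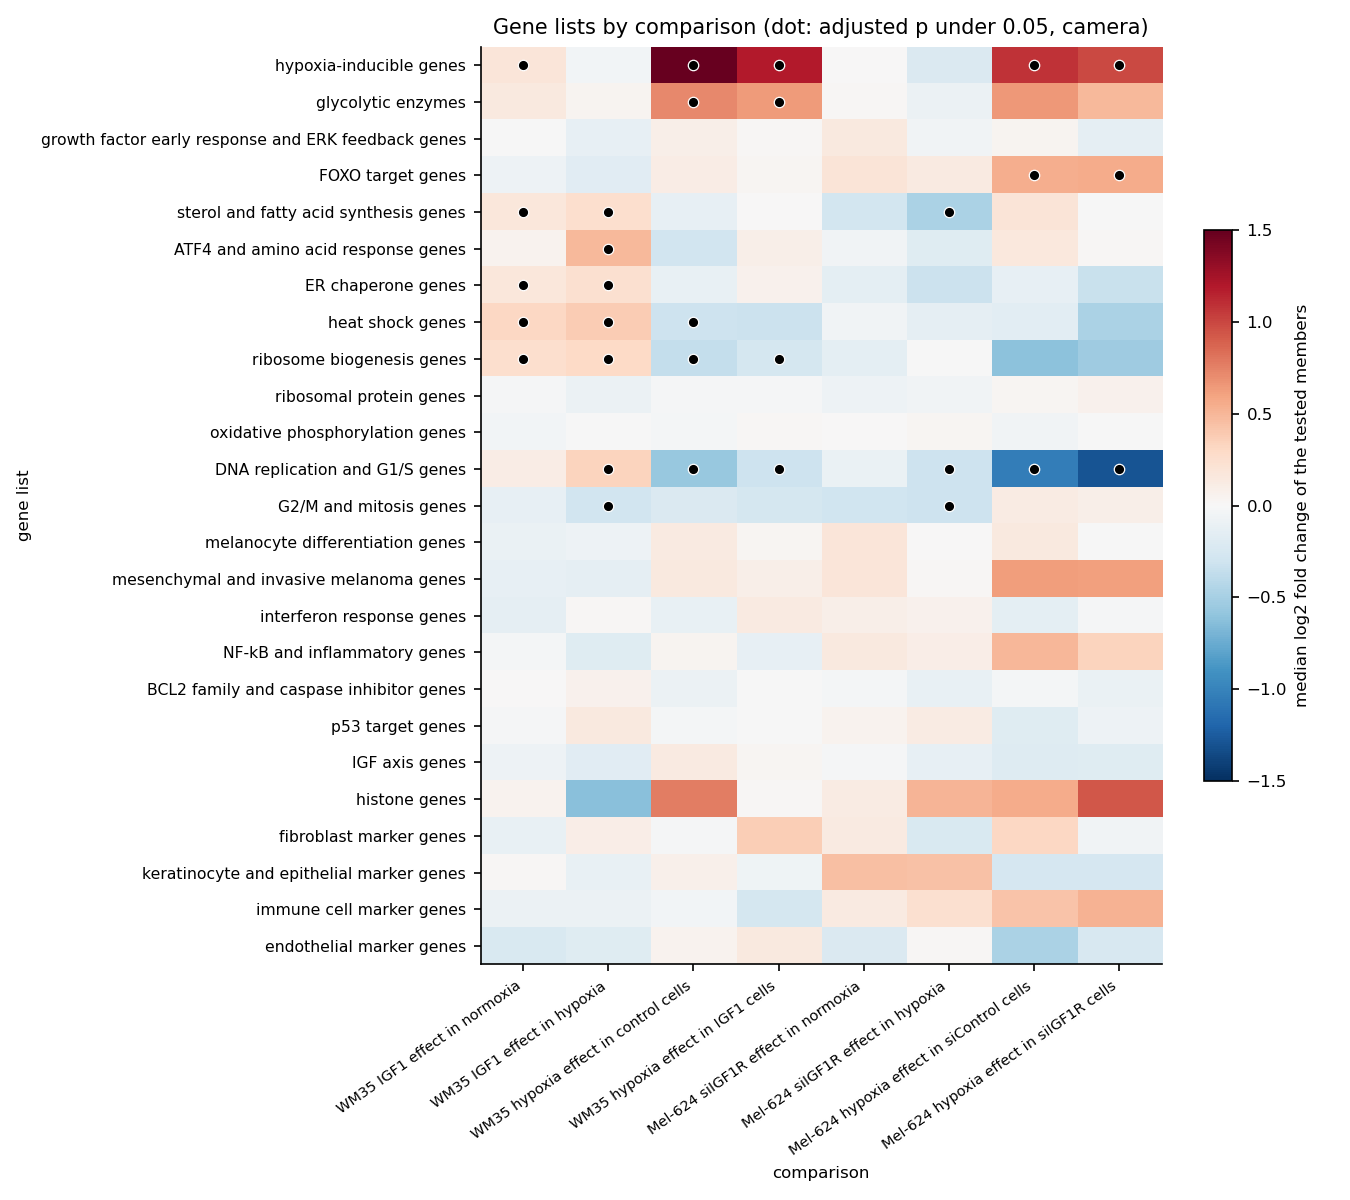
Median log2 fold change of the gene lists, 1 per line, in 8 comparisons, on a colour scale from -1.5 to 1.5, with a dot where camera gave an adjusted p below 0.05. Hypoxia-inducible genes have medians of 1.49 and 1.18 in WM35 and 1.08 and 1.00 in Mel-624 under hypoxia.

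The knockdown effect differed between hypoxia and normoxia for 76 genes, 21 higher and 55 lower in hypoxia. EGR1 (-1.30), FOS (-1.15) and NR4A3 (-1.32), immediate early genes, the matrix gene CCN1 (-1.17) and HSPA1B (-1.43) had lower effects in hypoxia, and SIN3A, a corepressor gene, a higher one (0.88), with adjusted p between 0.0079 and 0.016. Early response genes had 0 higher and 4 lower of 26 (0 and 7 adjusted over the list alone), adjusted p = 0.078 with an estimated correlation and 0.0024 with the preset one. The count of 76 was 23, 48 and 38 without normoxia siControl A, B and C, 28 and 31 without normoxia siIGF1R B and C, 33, 27 and 30 without hypoxia siControl A, B and C, and 32 and 33 without hypoxia siIGF1R A and C. With no detection filter it was 32, and with detection on all 12 arrays 136. At an unadjusted p under 0.05 there were 1411 genes.

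**Figure D3:**
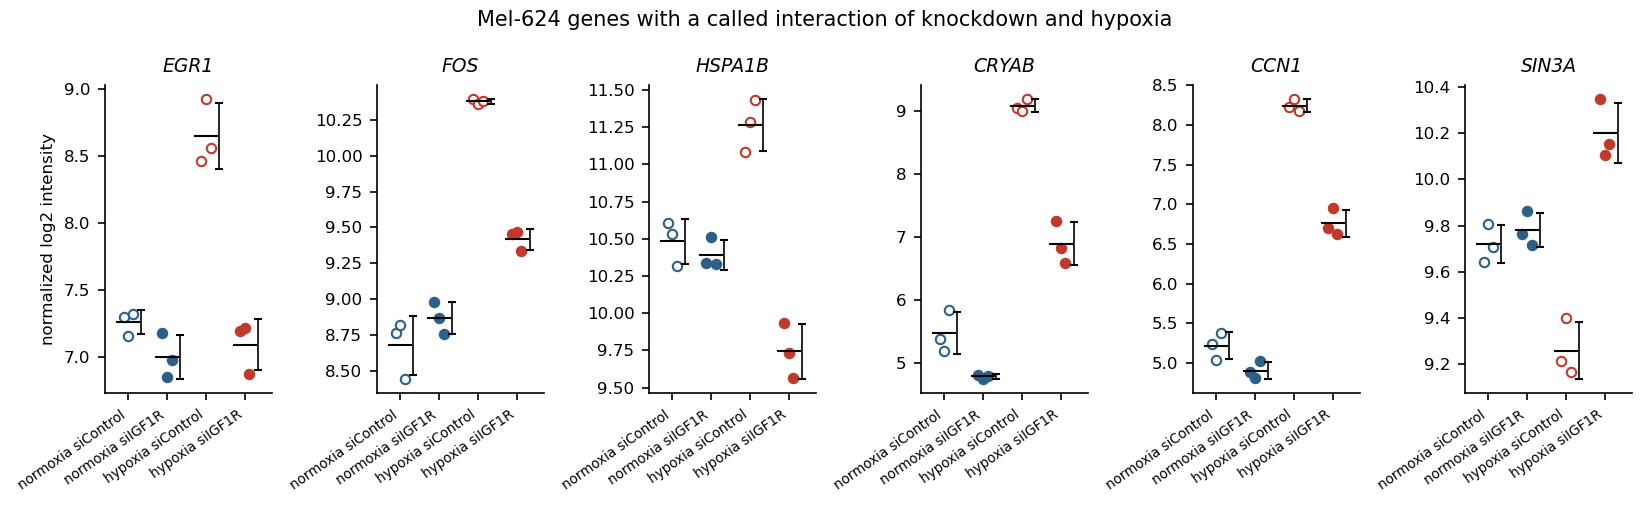
Log2 intensity of EGR1, FOS, HSPA1B, CRYAB, CCN1 and SIN3A on each Mel-624 array, with 1 point per array, open for siControl, filled for siIGF1R, blue for normoxia and red for hypoxia, and with black lines for means and bars for the SD of 3 arrays. The difference of the knockdown effects, hypoxia minus normoxia, is -1.30 for EGR1, -1.15 for FOS and 0.88 for SIN3A.

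Low oxygen in Mel-624 siControl cells raised CRYAB by 3.61 ± 0.17 (adjusted p = 2e-08), VASN by 3.09 ± 0.11, the kinase gene PIM1 by 2.87 ± 0.12 and CCN1 at least 6.51-fold from undetected. It raised IGF1R itself by 1.41 ± 0.18 (adjusted p = 2.8e-05). NDRG1 rose by 1.58 ± 0.10, VEGFA by 1.32 ± 0.15, SLC2A1 by 1.30 ± 0.14 and ADM by 0.71 ± 0.09. The cell cycle genes E2F2 (-3.91 ± 0.17), CDC25A (-3.09 ± 0.11) and CDC7 (-2.36 ± 0.15) fell. DNA replication genes had 0 up and 24 down of 27 (0 and 24 adjusted over the list alone, median -1.04, camera adjusted p = 0.0027), CHAF1B by -2.01 ± 0.10 and FEN1 by -1.74 ± 0.09. Hypoxia-inducible genes had 22 up and 0 down of 25 (22 and 0 adjusted over the list alone, adjusted p = 0.0039), BNIP3 by 1.90 ± 0.11 and P4HA1 by 1.60 ± 0.10. FOXO target genes had 17 up and 1 down of 24 (17 and 1 adjusted over the list alone, median 0.54, adjusted p = 0.0039), with YPEL2 at 1.86 ± 0.10 and FBXO32 at 1.42 ± 0.09. Glycolytic enzymes had 14 up and 0 down of 17 (14 and 0 adjusted over the list alone), adjusted p = 0.068 with an estimated correlation and 1.4e-06 with the preset one. Ribosome biogenesis genes had 1 up and 17 down of 24, adjusted p = 0.068 with an estimated correlation and 9.5e-05 with the preset one. In all 4793 genes were called, 2154 up and 2639 down, 4657 with non-overlapping arrays.

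In siIGF1R cells hypoxia raised PIM1 by 3.04 ± 0.12, VASN by 2.30 ± 0.11, NDRG1 by 1.83 ± 0.10, VEGFA by 1.07 ± 0.15 and SLC2A1 by 0.83 ± 0.14. It lowered E2F2 at least 13.5-fold to undetected, CDC25A by -2.66 ± 0.11 and the melanocyte channel gene TRPM1 by -2.64 ± 0.13. IGF1R moved by 0.37 ± 0.18 (adjusted p = 0.10). DNA replication genes had 0 up and 25 down of 27 (median -1.29, adjusted p = 0.0014), FOXO target genes 18 up and 3 down of 24 (adjusted p = 0.0080) and hypoxia-inducible genes 20 up and 1 down of 25 (adjusted p = 0.0098). In all 4644 genes were called, 2109 up and 2535 down, 4480 with non-overlapping arrays. Hypoxia effects without and with knockdown correlated over genes at r = 0.878, with 3582 genes called the same way (1209 by independence) and 16 in opposite directions.

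Adding IGF1 to WM35 and lowering its receptor in Mel-624 were set side by side over 8391 genes tested in both lines. ABTB1 fell by 1.13 with IGF1 and rose by 1.37 with siIGF1R, TXNIP moved by -0.74 ± 0.07 and 1.10 ± 0.07, DHCR7 by 0.77 and -0.70, PSAT1 by 0.47 and -0.74, and HBP1 by -0.74 and 0.68. Other genes moved the same way in both, FZD2 by -0.60 and -1.27 and SLCO4A1-AS1 by -1.51 and -0.59. Of genes called in both lines 374 changed in opposite directions and 179 in the same direction, where 224 would in each by independence. Of the WM35 genes that rose with IGF1 and were tested in both, the 100 with the smallest p were taken. With siIGF1R 11 of these rose and 36 fell (camera adjusted p = 0.032). Of the 100 with the smallest p among genes that fell with IGF1, 38 rose and 14 fell (adjusted p = 0.046). Over all genes the averaged effects correlated at r = -0.146 (rho = -0.134). Of 100 splits of the Mel-624 samples 19 gave an r as far from 0, so chance cannot be excluded for that correlation. Treatments, durations and chips differed between the lines.

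**Figure D4:**
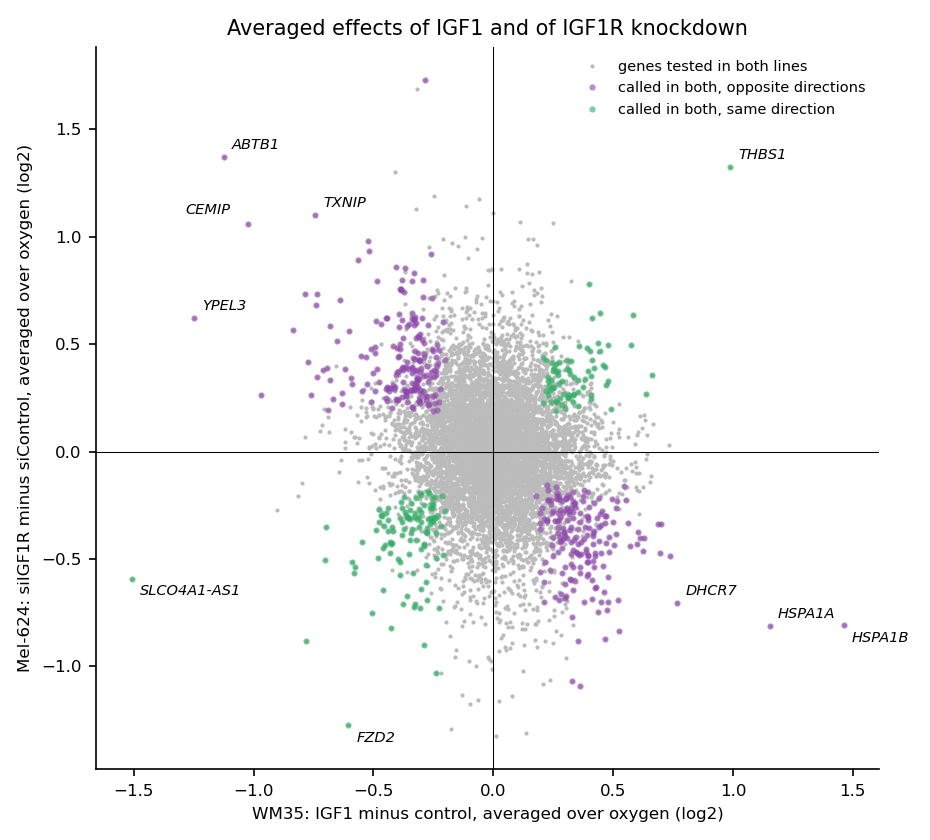
Log2 fold change of each gene with IGF1 in WM35 (horizontal) against that with siIGF1R in Mel-624 (vertical), both averaged over oxygen, with genes called in opposite directions in purple and in the same direction in green. ABTB1 lies at -1.13 and 1.37, and 374 genes are purple and 179 green.

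Hypoxia effects in control cells of the 2 lines correlated over the same genes at r = 0.311 (rho = 0.293). In those 8391 genes 828 were called the same way (444 by independence) and 206 in opposite directions (436 by independence). Hypoxia-inducible genes differed between lines by -0.14 (Mel-624 minus WM35, camera adjusted p = 0.247), and DNA replication genes by -0.52 (adjusted p = 0.031), with medians of -0.57 and -1.07 over the members tested in both.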

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

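In this part, the tests of brightness, of the main axis within groups, of opposite manipulation, of a single array, of array scaling and of handling stress were chosen only after the results were seen, and the splits of the samples were planned. No single-sample outlier test was run, since groups held 3 samples.

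The effect of IGF1 in WM35 differed between hypoxia and normoxia in 5 genes. FST, which encodes an activin antagonist, had the higher effect in hypoxia (0.85), and SPRY1 (-1.43), SNHG7 (-1.21), REEP4 (-1.21) and P2RY11 (-0.95) the lower one. The count was 0 without any 1 of the 6 normoxia arrays or of hypoxia IGF1 A and B, 9 and 2 without hypoxia control A and B, and 1 without hypoxia IGF1 C. As gene groups, ATF4 and amino acid response genes differed by a median of 0.37 and hypoxia-inducible genes by -0.17. Of 100 splits of the 12 samples 1 gave as many called genes, the real one, and the highest other gave 2. In the fit without a replicate block the count of 5 was thus larger than in every other drawn split. That does not exclude chance in the spread between samples, since the count was small and fell to 0 without 1 array in most cases. With the replicate letter as a block the count was 2, no more than that highest other, and without both WM35 libraries standing apart it was 0, and no splits were drawn for those fits. Camera gave adjusted p = 0.0093 for both lists, 0.051 for hypoxia-inducible genes without normoxia control C, and 0.054 and 0.098 without both WM35 libraries standing apart, the highest over the alternatives, whose lowest were 0.00295 and 0.0091.

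The effect of siIGF1R in Mel-624 differed between hypoxia and normoxia in 76 genes. The largest differences upwards, as hypoxia minus normoxia, were in EED (1.46), PALS2 (1.06), BORCS6 (1.06), MCOLN2 (1.05), PPP1R12C (1.04), ALG11 (1.02), DLX5 (1.01), RCL1 (0.91), BPGM (0.90) and SIN3A (0.88), EED and SIN3A being parts of chromatin repressor complexes. The largest downwards were in CRYAB (-1.505), HSPA6 (-1.48), HSPA1B (-1.43), NR4A3 (-1.32), EGR1 (-1.30), TRPM1 (-1.22), BMPR2 (-1.22), CCN1 (-1.17), SCG2 (-1.16) and FOS (-1.15), which include heat shock genes and immediate early genes. SIN3A, HSPA1B, NR4A3, EGR1, CCN1 and FOS were called under all alternatives run, while the other 14 lost the call in at least 1, ALG11 and CRYAB without normoxia siControl A. The count of 76 was 23, 48 and 38 without normoxia siControl A, B and C, 28 and 31 without normoxia siIGF1R B and C, 33, 27 and 30 without hypoxia siControl A, B and C, and 32 and 33 without hypoxia siIGF1R A and C. Of 100 splits of the samples 1 gave as many genes, the real one, and the highest other gave 1. So chance in the spread between samples can be excluded for the count.

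Several explanations of those 76 genes were weighed. A single deviating array as the whole cause would leave hardly any called genes when left out, yet at least 23 genes were called without each array in turn, against 1 in the highest other split. The scaling chosen here as the whole cause would leave hardly any under another, yet 62 genes were called with the deposited normalized values and 109 without further background correction, with the median of all genes shifting by at most 0.0070. Stress in handling the hypoxic siControl cells predicts heat shock and immediate early genes that are highest in that group. Members of the fixed lists made up 7.89% of the 76 (4 of 26 early response and 2 of 13 heat shock genes tested), and all 6 were highest in that group. That share counts listed genes only and is a lower bound, since HSPA6, NR4A3 and CCN1, and MAFF and DUSP1, chosen after their values were seen, are related genes outside the lists and were also highest there, as were 32 of the 76 in all. Genes picked for a lower knockdown effect in hypoxia tend to be highest in that group by construction, so that position is no test of handling. Handling may explain such genes, but a biological response in those cells predicts the same and cannot be told apart from it. IGF1R itself also fell further with knockdown in hypoxia than in normoxia, though that difference was not called. Whether unequal depth of knockdown played a part in the 76 genes was not tested.

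The hypoxia response of control cells differed between the lines in 2951 of 8391 genes, and 206 genes were called in opposite directions. DNA replication and G1/S genes differed by a median of -0.52 (Mel-624 minus WM35). Length of culture, transfection and chip differed with the line, so those were not separated from it.

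IGF1-responsive genes in WM35 were set against technical differences, since the normoxia controls had the brightest arrays. Brightness would require the effect to vanish in hypoxia, where the control arrays averaged 259 and the IGF1 arrays 256. Yet 94.0% of the genes called in normoxia had the same sign in hypoxia, against 66.4% of uncalled genes. That share pools genes, so it does not cover results seen in normoxia only. Brightness stays open for the hypoxia-inducible list, called in normoxia but not in hypoxia, and for its difference between oxygen levels. The main axis of spread within groups as the whole cause would require nearly all genes called for the averaged effect to change the way they load on that axis. Of those genes 57.2% did, and between 52.7% and 63.7% with 1 array left out. The axis was taken in the direction that matched more genes, so 50% is the lowest share possible. Both tests argue against those causes for the whole set, while a part played by the axis and a difference in culture between dishes of a group remain open. Position on the chip, which went with group, remains open as well.

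Every count of called genes was set against other splits of the samples. For IGF1 in normoxia the real split gave 151 called genes and the highest other 1, and in hypoxia 867 and 0. For hypoxia the counts were 1981 and 0 in control and 1488 and 0 in IGF1 cells. In Mel-624 they were 1483 and 0 for siIGF1R in normoxia, 2399 and 0 in hypoxia, 4793 and 0 for hypoxia in siControl and 4644 and 0 in siIGF1R cells. In each, 1 of 10 splits gave a count as large, the real one, and 10 splits are too few for a share under 0.05. For the averaged effects 1 of 100 splits gave a count as large, the real one, with 1483 against a highest other of 249 in WM35 and 3218 against 783 in Mel-624. So chance in the spread between samples can be excluded for both.

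The opposite changes in the 2 lines were weighed last. A shared axis of spread within groups would have to produce the negative correlation, but with both axes removed r was still -0.146. Opposite manipulation of 1 pathway was left undecided. The 374 genes called in opposite directions, against 224 by independence and 179 called the same way, are the pattern itself and no test of its cause. That explanation also asked for a share of splits under 0.05, and 19 of 100 splits of the Mel-624 samples gave an r as far from 0, with a highest other of -0.229. So chance cannot be excluded for the correlation, and a shared IGF1 response and a difference in growth rate, which the design did not vary, both remain open. For hypoxia across lines r was 0.311 against a highest other of 0.281, 1 of 10 splits was as large, the real one, and 10 splits are too few for a share under 0.05.

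Probes without a gene symbol, which the comparisons above leave out, also responded. Of them 183 were called for IGF1 averaged over oxygen and 336 of 4637 for hypoxia in WM35 control cells, 751 for siIGF1R averaged over oxygen and 1457 of 4488 for hypoxia in Mel-624 siControl cells.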

How the results depend on the processing

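The alternatives with the WM35 libraries standing apart left out (normoxia control C and hypoxia control A), with the within-group axis removed and with lists retested without each array were chosen only after the results were seen. Of 931 results for named genes, 879 of them called, 1 reversed: TP53I3 under hypoxia in WM35 with IGF1 was -0.034 with the mean of its probes, against 0.41, and the cause was not tested. Calls of named genes were lost in 65 of the 931 with the deposited values, 61 with no detection filter, 33 with the replicate block, 28 with the mean of probes and 3 without further background correction. They were lost in 59 of 697 with only the groups compared, 37 of 406 without both libraries standing apart and 838 of 11157 with 1 array left out. Of 300 list results, 44 of them called, 10 lost the call and 4 gained it with the deposited values, 1 and 2 did without further background correction, 0 and 13 with no detection filter, 4 and 2 with the mean of probes, 7 and 2 with the replicate block and 1 and 10 with the within-group axis removed. Of fewer or more results, 2 and 10 of 294 did with detection on all 12 arrays, 10 and 1 of 150 without both libraries standing apart, and 72 and 21 of 3600 with 1 array left out. None lost it and 45 gained it with the preset correlation, and 127 gained it with fry, which tests each list by itself and whose p-values changed with the order of the design's columns.

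Counts of called genes moved by more than 1.5 times, for causes not tested, as follows. With no detection filter they were 90 for IGF1 in normoxia and 32 for the Mel-624 interaction. With detection on all 12 arrays they were 249 and 136. With the replicate letter as a block they were 87 and, for the WM35 interaction, 2, and whether letters pair the arrays was not settled. A deviation was most like its own letter in 5 of 12 WM35 and 8 of 12 Mel-624 arrays, and Mel-624 deviations correlated at a mean of 0.059 within and -0.029 between letters. In Mel-624 5 of 18 pairs of the same letter correlated above 0.1, against 0 of 36 of different letters. In WM35 8 of 18 and 12 of 36 did. So a pairing in Mel-624, which the main fit leaves out, is possible. With only the groups compared, which leaves fewer arrays for the variance, IGF1 gave 31 in normoxia and 436 in hypoxia. With the deposited values the WM35 interaction gave 8, and without both libraries standing apart 0. With the axis removed, which raises counts by construction, WM35 gave 805, 1844, 2579, 3125, 2522 and 62 (IGF1 in normoxia, in hypoxia and averaged, hypoxia in control and in IGF1 cells, interaction), and the Mel-624 interaction 291. At a fold change of at least 1.5, which is stricter by construction, the first 5 of these gave 61, 257, 98, 738 and 557, and Mel-624 459, 831, 488, 2575 and 2457 in the same order. The hypoxia correlation across lines was 0.248 with no detection filter, which moved it from 0.311 by more than its jackknife SE of 0.027, also for a cause not tested.

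Without 1 array the counts, in that order, ranged from 26 to 196, 361 to 859, 1046 to 1530, 1383 to 2029, 909 to 1657 and 0 to 9 in WM35. In Mel-624 they ranged from 889 to 1573, 1666 to 2486, 2809 to 3166, 4221 to 4849, 4110 to 4654 and 23 to 64. The correlations across lines ranged from -0.167 to -0.128 and from 0.286 to 0.316. Signal over background limits what was tested, since on the array with fewest detected probes 29.5% were detected.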

Other observations

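Gene groups not described above are given here from camera with an estimated correlation. No test in this part was chosen after its result was seen.

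In WM35, hypoxia in control cells raised the histone gene H2BC5 by 1.94 ± 0.11 (adjusted p = 1.1e-07), and histone genes had 4 up and 0 down of 7 (4 and 0 adjusted over the list alone, list adjusted p = 0.129, 0.0082 with the preset correlation). IGF axis genes had 3 up and 0 down of 10 (3 and 0 adjusted over the list alone, list adjusted p = 0.201), with the IGF-binding protein genes IGFBP6 at 0.89 ± 0.09 and IGFBP2 at 0.82 ± 0.11. Mesenchymal and invasive melanoma genes had 4 up and 3 down of 18 (6 and 5 adjusted over the list alone, list adjusted p = 0.778), with the matrix gene FN1 at 1.20 ± 0.18. NF-kB and inflammatory genes had 3 up and 6 down of 14 (3 and 6 adjusted over the list alone, list adjusted p = 0.597), with a median of 0.04, a mean of -0.20 and a test direction of down, and the chemokine gene CXCL8 fell by 0.93. Early response and ERK feedback genes had 4 up and 2 down of 29 (adjusted p = 0.201), melanocyte differentiation genes 2 up and 1 down of 10 (adjusted p = 0.597), interferon response genes 3 up and 1 down of 16 (adjusted p = 0.973) and p53 target genes 1 up and 1 down of 16 (adjusted p = 0.983). Oxidative phosphorylation genes had 1 up and 2 down of 24 and ribosomal protein genes 1 up and 0 down of 20 (adjusted p = 0.778 for both). BCL2 family and caspase inhibitor genes had 0 up and 0 down of 13 (adjusted p = 0.778).

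In Mel-624, siIGF1R averaged over oxygen raised the endothelin receptor gene EDNRB by 0.92 ± 0.07 (adjusted p = 1.4e-06) in melanocyte differentiation genes, which had 6 up and 1 down of 21 (6 and 1 adjusted over the list alone, list adjusted p = 0.518). It raised the interferon-induced gene IFIT3 by 0.99 ± 0.10, the NF-kB inhibitor gene TNFAIP3 by 0.68 ± 0.07 and the IGF2 receptor gene IGF2R by 0.70 ± 0.07, and lowered CXCL8 by -0.96 ± 0.10. Interferon response genes had 3 up and 2 down of 15, NF-kB genes 3 up and 1 down of 7 (list adjusted p = 0.619 for both), IGF axis genes 1 up and 2 down of 9 (list adjusted p = 0.754) and histone genes 4 up and 0 down of 8 (list adjusted p = 0.508). Hypoxia in siControl cells raised the invasion genes TWIST1 by 0.91 ± 0.08 and VIM by 0.95 ± 0.10 among mesenchymal genes, with 9 up and 0 down of 12 (9 and 0 adjusted over the list alone, list adjusted p = 0.071, 0.00016 with the preset correlation). It raised the apoptosis gene BIK by 1.47 ± 0.14 and lowered BCL2 by -1.02 ± 0.11, and BCL2 family genes had 3 up and 4 down of 15 (list adjusted p = 0.912). GADD45A rose by 1.77 ± 0.14 and TIGAR fell by -1.77 ± 0.10, and p53 target genes had 4 up and 5 down of 13 (list adjusted p = 0.699). Ribosomal protein genes had 0 up and 0 down of 20 (list adjusted p = 0.693) and oxidative phosphorylation genes 4 up and 3 down of 24 (list adjusted p = 0.912).

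Marker genes of other cell types were tested for changes under hypoxia. Such changes do not measure purity, since other cells present equally at both oxygen levels would give none. In WM35 under hypoxia the macrophage marker CD68 rose by 0.69 ± 0.09, HLA-DRA fell by -0.84 ± 0.10, the endothelial receptor gene KDR fell by -0.90 ± 0.11 and the fibroblast-associated collagen gene COL6A3 rose by 0.67 ± 0.10. List p-values in that comparison were 0.778 for fibroblast markers (2 up and 1 down of 5), 0.770 for keratinocyte and epithelial markers (0 up and 0 down of 4), 0.973 for immune cell markers (1 up and 1 down of 4) and 0.778 for endothelial markers (0 up and 1 down of 4). In Mel-624 siControl cells under hypoxia they were 0.694 (2 up and 1 down of 3), 0.806 (0 up and 0 down of 1), 0.276 (2 up and 0 down of 4) and 0.542 (0 up and 1 down of 1), in the same order. CD79A rose there by 0.90 ± 0.14. With 1 to 5 members tested per list, and only for changes, the presence of other cells was neither shown nor excluded.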
